A study of Homo sapiens with 2 samples.

How the data were processed

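The arrays measured RNA from the Ago2 immunoprecipitate and total RNA of Jurkat cells that overexpressed miR-21 or carried an empty vector, as 2 samples of 2 arrays each. Per the labels, total RNA was taken before the immunoprecipitation, the IP used cleared cell lysates, and 40 to 100 ng of RNA was amplified and labelled with Cy3 or Cy5. A control immunoprecipitation with a non-specific antibody is mentioned in the labels' protocols and was not analysed here. Groups and the dye of each RNA came from the labels. The second array of each sample is a dye swap of the same RNA extracts, so the 2 arrays were counted as 1 replicate. The arrays with exchanged dyes ran opposite to each other, and arrays of both populations with the same dyes ran the same way. This would look the same if IP and total RNA were exchanged on every array, so the directions were taken from the labels.

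The deposited files are scanner output, 1 per array. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1 on array design 028004, at a scan resolution of 3 micrometres. The deposited signals are intensities on a linear scale (median foreground and local background per spot and dye). The files also hold processed signals, which per the file headers are intensities already background-subtracted and dye-normalized by the scanner software, and a deposited log10 ratio of red over green made from them, which served to check the direction of the ratios. The plan had named mean signals; the deposited files give median signals, and these were used. What further processing the submitters applied for their own analysis is not given in the sources used here.

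Each array held 62976 features, of which 58717 were non-control spots for 42405 distinct probes. Between 58086 and 58188 non-control spots per array carried no outlier flag. Saturated spots numbered 4 on 1 EV array and 0 on the others. In R 4.3.3 with limma 3.58.1, background was corrected by normexp with an offset of 50, and each array was normalized by loess with weight 0 for control and outlier spots. Log ratios were turned to IP over total. For total RNA and IP RNA by themselves, arrays were scaled with limma's Aquantile method and separated into channels. Outlier spots were left out and spots of a probe averaged. The offset pulls ratios of dim spots toward 0, so differences of dim genes are understated. A gene entered a comparison where each RNA involved was well above background, per the scanner flags, on both arrays, for at least 50% of a probe's spots. The number of arrays limits the precision: with 2 orientations of 1 sample, the SD covers technical error, with medians over genes of 0.146 for IP over total in miR-21 cells, 0.111 in EV cells, 0.131 for their difference and 0.090 for total RNA. Slide, scan and grid version go with the population, so no fit with the slide as a block was possible.

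Probes were named through the accession in the files and the RefSeq gene table given for the series, whose assembly is GRCh38.p14; the array's grid is annotated to hg19 per the file headers, so the table was used for names only and no coordinates are given. A single symbol was found for 25430 probes, several for 30 and none for 16945, of which 8263 are lincRNA probes; 4189 probes carry different accessions on the grids of the 2 slides, and both were looked up. This left 35183 features, 19479 with a symbol. A gene's value is that of 1 probe, chosen among probes measured in all 4 RNAs first and then by the highest mean signal. Of 2446 genes with more than 1 measured probe, 120 had probes that differed in sign past 0.58 on the log2 scale, none of them among the genes named by rank or as known targets.

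With 1 sample per population no test was run. Genes were called by a size rule, a mean log2 of at least 1 in size with each orientation at least 1.5-fold the same way. Gene lists were written from general knowledge, not from a database: known miR-21 targets, miR-17-92 targets, apoptosis-promoting and apoptosis-restraining genes, Argonaute and microRNA machinery, T-cell receptor signalling, T-ALL transcription factors, cell cycle, interferon response, stress and immediate-early genes, oxidative phosphorylation, proteasome, nuclear and other noncoding RNAs, and markers of B, myeloid, erythroid and epithelial or stromal cells. Ribosomal protein, mitochondrial ribosomal, replication-dependent histone, ZNF, and lincRNA or LOC features were taken by name. Whether an entry of the miR-21 target list was first found in these samples is not known here. For each list with at least 5 measured genes, the median was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. Percentiles describe these arrays and are not p-values. Lists can share genes; the miR-21 and miR-17-92 target lists share 3. Named genes followed a fixed rule: the 12 highest and 12 lowest differences with a symbol, up to 12 known miR-21 targets past the size rule in any comparison, PDCD4, BTG2, SPRY2, TIA1, CASP8AP2 and VMP1, the 10 highest and 10 lowest for IP over total in both populations and for total RNA, and up to 4 members per list. A few genes that this rule selects are not reported here. The highest and lowest differences and total-RNA changes were ranked by the smaller of the 2 orientations, and IP over total by the smaller of the 2 populations. The rule, the lists, the comparisons and the first set of alternatives were fixed before the data were examined. PCBP1, named in a caption as the lowest known target, was chosen after its value was seen.

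The steps were tested on simulated data: EV arrays with added technical noise stood in for miR-21 arrays. The stand-ins kept the signals and background flags of the EV arrays, which were brighter than the real miR-21 arrays. They also held no difference between slides. The rates below therefore describe arrays like the EV arrays and may not hold for the real comparison. For the difference in IP over total, over 28491 probes, the size rule recovered 72% of probes planted 3-fold higher, 55.1% of those 3-fold lower, 48% of those 2.30-fold higher and 54% of those 2.30-fold lower, and called 0 unplanted probes. In the brighter part of the probes (14246) it recovered 100% in both directions at 3-fold, and 85.2% and 93.1% at 2.30-fold. Estimates were shrunk, with a median of 1.31 for a planted 1.58. Of 100 random lists of 50 genes, 5 lay outside the middle 95%.

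Alternatives covered the within-array normalization, the background correction, the scanner software's processed signals, the filter on dim probes, each dye orientation alone, the mean of a gene's probes, the size threshold, outlier spots, and quantile or 75th percentile scaling of channels. The processed signals were centred again in each array on the median of its unflagged non-control spots. That setting therefore shares its centring with median centring over all spots. A planned comparison of genes with and without a miR-21 site in the 3' untranslated region needed transcript sequences and was not run. Tables were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.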

Results

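The data were 4 two-channel expression arrays from Jurkat cells, an established human acute leukemic T-cell line, that overexpressed the microRNA miR-21 or carried an empty vector (EV). Ago2, the Argonaute protein that holds microRNAs on their target transcripts, was immunoprecipitated (IP) from cell lysates. On each array the RNA from the Ago2 IP was hybridised against total RNA of the same cells, and the dyes were exchanged on the second array of each population. The title of the series asks which apoptosis-associated genes are miR-21 targets. Each population was 1 sample on 2 arrays that shared the same pair of RNA extracts, so n = 1 per population. No difference has a replicate check, and no p-value is given. Values are mean log2 ratios over the 2 dye orientations, and ± gives the SD over these orientations, which covers labelling and hybridisation error only. A gene was called higher or lower where the mean was at least 1 on the log2 scale (2-fold) and each orientation was at least 1.5-fold the same way.

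The miR-21 arrays were dimmer than the EV arrays. The 75th percentile of the background-subtracted IP signal was 191 and 167 on the miR-21 arrays against 707 and 891 on the EV arrays, and that of total RNA was 289 and 370 against 652 and 524. The IP channel was well above background at 53.5% and 54.0% of spots on the miR-21 arrays and at 72.3% and 82.3% on the EV arrays. Each population lay on its own slide with its own scan, so slide and population cannot be told apart in any comparison between them. IP and total RNA were both well above background for 16399 genes in miR-21 cells and for 24002 in EV cells, and all 4 RNAs for 16383. In miR-21 cells a further 388 probes were well above background in the IP only and 1978 in total RNA only. These carry only a bound, which reached 2-fold for 93 and 10 of them. The log ratios of the 2 orientations had r = 0.952 across genes in miR-21 cells and 0.916 in EV cells; genes are not independent replicates.

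The first comparison asked which transcripts were in the Ago2 fraction of each population. CD69, an early T-cell activation antigen, had an IP over total of 6.30 ± 0.15 in miR-21 cells and 4.79 ± 0.19 in EV cells, and BTG2, an anti-proliferative gene, had 4.92 ± 0.22 and 3.91 ± 0.08. NHLRC3 (5.57 ± 0.35 and 4.32 ± 0.20), C2orf69 (6.19 ± 0.22 and 4.14 ± 0.25) and WASL, an activator of actin nucleation (6.64 and 4.00 ± 0.14), were also among the 10 highest in both. MYLIP, BOD1, GPR137B, ZNF700 and MIR503HG completed these 10, with 3.79 to 4.27 in EV cells; GPR137B had 4.361 and 1.199 at its 2 probes in miR-21 cells. The 10 lowest in both included the glycolytic enzyme genes PFKL (-1.58 ± 0.16 in miR-21 cells, -1.59 ± 0.08 in EV cells) and ENO1 (-2.06 ± 0.14 and -1.47 ± 0.14), and the coat protein gene SEC13 (-1.58 ± 0.21 and -1.49 ± 0.26). A4GALT, UTS2R, ZNF467 (-0.15 at its other probe in miR-21 cells), CEBPD and UNCX were also among them.

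In miR-21 cells 2518 genes were higher in the IP than in total RNA and 1617 were lower; in EV cells 1445 were higher and 592 lower. Among the 16383 genes measured in both, 920 were higher in both populations, against 213.6 for independent lists of these sizes, and 178 were lower in both, against 57.7. The split of higher and lower depended on the centring. With the scanner software's own processed signals, centred again on the median over all spots, it was 2858 and 3529 in miR-21 cells and 1761 and 1152 in EV cells. When loess was replaced by median centring, it was 1127 and 5576 in miR-21 cells and 1831 and 352 in EV cells. The processed signals moved the median of all genes in miR-21 cells to -0.23 and median centring moved it to -0.54; with median centring over probes above background, which left it at -0.02, 36.8% of the calls in miR-21 cells were higher, against 60.9% in the main setting. The log ratios were spread more widely in miR-21 cells, with an SD over genes of 1.03 against 0.681 in EV cells, and they had r = 0.585 between the populations across genes.

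**Figure D1:**
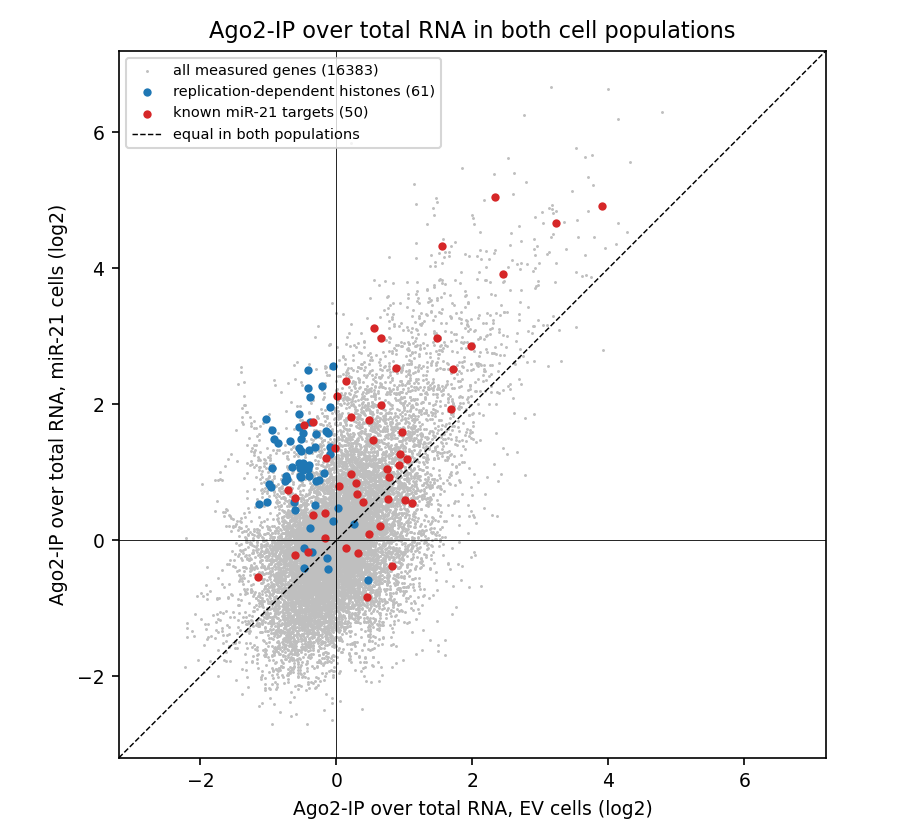
Each grey point is a gene measured in all 4 RNAs, at its mean log2 ratio of Ago2-IP over total RNA in EV cells (x axis) and miR-21 cells (y axis); red points are the 50 known miR-21 targets, blue points the 61 replication-dependent histone genes, and the dashed line marks equal ratios. The red points lie mostly above the line, with a median of 1.15 in miR-21 cells, and the blue points lie mostly at negative values in EV cells and positive values in miR-21 cells, where the median of 1.07 became -0.03 with median centring over probes above background and -0.56 with median centring over all spots, both above all random lists.

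Targets of the miR-17-92 cluster, a group of microRNAs that T-cell leukemia lines express, served as a positive list for Ago2 binding. In EV cells 20 of 36 measured members were higher in the IP and 0 were lower, with a median of 1.18, and in miR-21 cells 23 of 31 were higher and 0 lower, with a median of 1.60. Both medians exceeded all of 10000 random lists matched on expression. The autophagy gene ATG16L1 (4.68 ± 0.11 in miR-21 cells, 3.34 ± 0.08 in EV cells) and the transcription factor gene ZBTB4 (4.23 ± 0.14 and 3.13 ± 0.09) had large values in both. Zinc finger genes named ZNF were another group with many enriched members: 137 of 319 were higher and 10 lower in miR-21 cells (median 0.70, 100th percentile of random lists), and 101 of 405 were higher and 5 lower in EV cells (0.36, 100th percentile). ZNF625 reached 5.40 ± 0.10 in miR-21 cells, and ZNF850 reached 3.92 ± 0.02 in EV cells. Known miR-21 targets were enriched already in EV cells, where 13 of 55 were higher and 1 lower (median 0.48, 100th percentile); in miR-21 cells 27 of 50 were higher and 0 lower (1.15, 100th percentile). Ribosomal protein genes lay below their matched lists, with medians of -0.53 in EV cells (19 lower and 5 higher of 83, percentile 0.04) and -0.26 in miR-21 cells (11 lower and 8 higher, percentile 1.94). Genes of oxidative phosphorylation had a median of -0.77 in miR-21 cells (18 lower and 1 higher of 50, below all random lists) and -0.24 in EV cells (4 lower and 5 higher, percentile 13.3).

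The central comparison asked which transcripts were more in the Ago2 fraction, relative to total RNA, when miR-21 was overexpressed: the log2 IP over total in miR-21 cells minus that in EV cells, taken between arrays of the same dye orientation. Known miR-21 targets were shifted up as a group. Of 50 measured members, 20 were higher and 2 lower, 41 had a difference above 0, and the median was 0.74 (0.81 with the IP in Cy3 and 0.66 with the IP in Cy5), above all random lists drawn. The deubiquitinase gene YOD1 (2.78 ± 0.02), PLEKHA1 (2.71 ± 0.11), the PI3-kinase subunit gene PIK3R1 (2.57 ± 0.39) and the chromatin organiser gene SATB1 (2.32) had the largest differences. PDCD4, a pro-apoptotic tumour suppressor and one of the best-studied miR-21 targets, had a difference of 1.38 ± 0.07, from 1.36 ± 0.06 in miR-21 cells and -0.02 ± 0.13 in EV cells. RPS6KA3 (2.17 ± 0.11, with 0.81 at the lower of its 2 probes), SKI (1.65 ± 0.12), the NF-kappaB inhibitor gene TNFAIP3 (1.49 ± 0.21), SKP2 (1.46 ± 0.08), ZNF367 (1.44 ± 0.17) and BTG2 (1.01 ± 0.30) were also higher. TGFBR2 (0.87 ± 0.10), TPM1 (0.79 ± 0.16, with -0.31 at the lowest of 3 probes) and TIA1, a promoter of apoptosis (0.94 ± 0.14), did not reach the size rule. The same held for CASP8AP2 (0.56 ± 0.08) and for SPRY2 (-0.57 ± 0.25). TGFBR2 and TPM1 were negative with median centring (-0.45 and -0.36) and with both populations brought to the same spread (-0.05 and -0.02). The list's median was -0.11 when loess was replaced by median centring, which moved the median of all genes to -0.74; relative to all genes it was then 0.64, against 0.72 in the main setting, again above all random lists. The processed signals moved the median of all genes in the difference to -0.11, and median centring over probes above background moved it to -0.16. With median centring over all spots BTG2 reversed to -0.28 and SKP2 to -0.0063, and with both populations brought to the same spread BTG2 reversed to -0.69 and ZNF367 to -0.066. VMP1, the gene whose transcription unit overlaps the miR-21 locus, had -0.74 ± 0.22; no feature on the array was named for miR-21 itself.

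**Figure D2:**
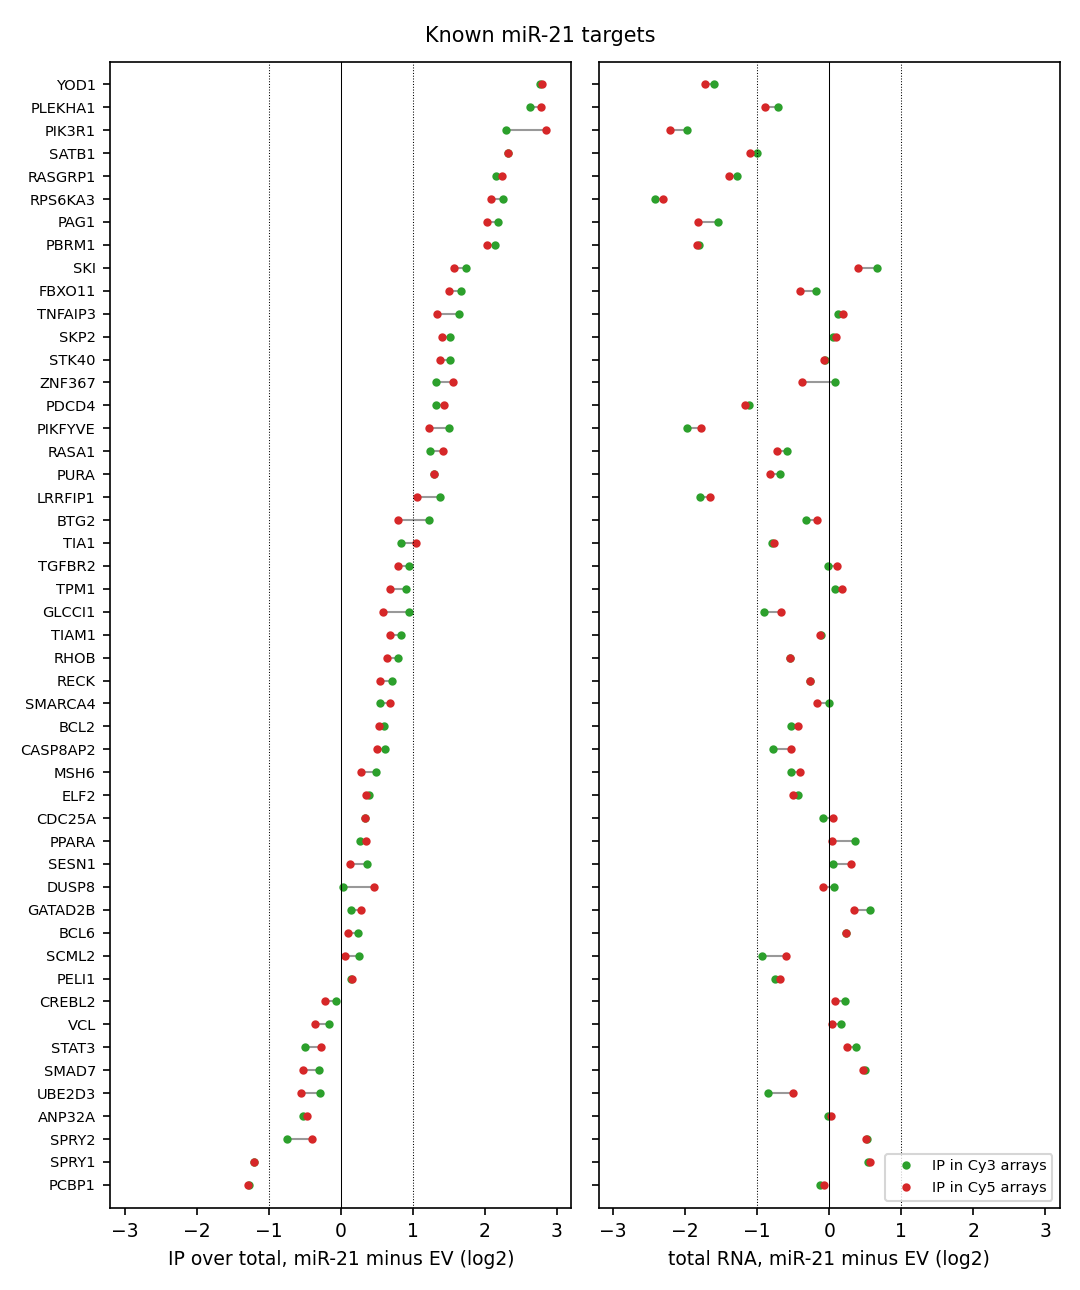
Each row is 1 of 49 known miR-21 targets, ordered by its IP over total difference; the left panel gives the log2 difference in IP over total and the right panel that in total RNA (miR-21 minus EV cells), with 1 point per dye orientation and dotted lines at 1 and -1. In the left panel 40 of 49 genes lie above 0, from -1.28 for PCBP1 to 2.78 for YOD1, and in the right panel 10 genes are called lower and 0 higher; with median centring the median of the whole list was -0.11 in IP over total and 0.13 in total RNA.

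Over all genes the difference was higher for 1936 of 16383 and lower for 1425. This split was 2510 and 2882 with the scanner software's processed signals, 397 and 6421 with median centring over all spots, and 1353 and 3335 with median centring over probes above background. Among the 12 highest genes with a symbol, the splicing regulator MBNL1 had a difference of 4.10 ± 0.24 (17.2-fold), and the RNA-binding protein genes IGF2BP3 and RBMS1 had 3.63 ± 0.01 and 3.48 (1.95 at the lowest of RBMS1's 3 probes). The cyclin-dependent kinase gene CDK6 had 3.43 ± 0.07, and PTPRC, which encodes the leukocyte phosphatase CD45, had 3.55 ± 0.30, although its 4 measured probes ranged from 0.16 to 3.55. Zinc finger genes among the 12 were ZNF254 (3.57 ± 0.08, with 1.35 at the lowest of 3 probes), ZNF429 (3.50 ± 0.01), ZNF714 (3.32 ± 0.05, with 1.01 at its other probe) and ZNF644 (3.36 ± 0.15, with 0.36 at its other probe). ADAMTS7 (3.94 ± 0.28, with 1.64 at its other probe), LINC01001 (3.88 ± 0.45, with -0.45 at the lowest of 3 probes) and LCE1D (3.69 ± 0.22) had IP over total below -1.3 in EV cells and above 2.3 in miR-21 cells. These 3 had the highest mean log2 signals of the 12, at 16.46, 16.21 and 15.95. Their values were also alike in total RNA (-1.36, -1.31 and -1.48) and in IP RNA (2.58, 2.57 and 2.21). Whether their probes are separate measurements was not tested. All 12 were also called lower in total RNA of miR-21 cells, from -1.30 for IGF2BP3 to -2.72 for CDK6, which adds to their differences. IP RNA was called higher for all of them except CDK6, at 0.71. The 12 lowest were led by the autophagy gene GABARAPL2 (-3.28 ± 0.28), ZMYND19 (-3.12 ± 0.09), CIAO2A (-3.06 ± 0.38) and ERG28 (-3.03 ± 0.35). The origin recognition gene ORC6 had -2.88 ± 0.05, the signalosome subunit gene COPS8 -2.86 ± 0.04 (-1.14 at its other probe), the centromere protein gene CENPB -2.85 ± 0.16 and the ubiquitin-conjugating enzyme gene UBE2N -2.79 ± 0.06. The remaining 4, UNC50, DCTD, PDE6D and MGST3, lay between -2.63 and -2.83. All 24 kept their call with median centring of either kind, the processed signals, each dye orientation alone, the mean of a gene's probes and both populations brought to the same spread, but their sizes moved. With median centring over all spots MBNL1 had 2.54, IGF2BP3 2.23 (2.27 with the same spread), CDK6 1.74, ADAMTS7 1.52, LINC01001 1.51 and LCE1D 1.385, and GABARAPL2 had -4.52.

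Genes higher in the IP over total in miR-21 cells and also higher in the difference numbered 1419, of which 1184 had a symbol and 18 were known miR-21 targets. The difference joins 4 RNAs, so its parts were set apart. Of the 1936 genes with a higher difference, 1287 had IP RNA at least 1.5-fold higher in both orientations, 879 had total RNA at least 1.5-fold lower, and 339 had both. Of the 1425 with a lower difference, 1194 had lower IP RNA and 153 had higher total RNA by this measure. Among the 20 known targets with a higher difference, 12 had higher IP RNA and 13 had lower total RNA. PDCD4 had total RNA of -1.14 ± 0.04 and IP RNA of 0.24, PIK3R1 had -2.10 ± 0.17 and 0.48, and YOD1 had -1.66 ± 0.09 and 1.12. SKI, TNFAIP3 and SKP2 had IP RNA of 2.18, 1.64 and 1.54 with total RNA of 0.53, 0.16 and 0.08.

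Apoptosis genes, the subject of the title, had medians inside the middle 95% of random lists in the difference. Of 47 measured genes that promote apoptosis, 6 were higher and 7 lower, with a median of -0.02 at percentile 44.1 of random lists, and of 25 that restrain it, 4 were higher and 1 lower, with a median of -0.12 at percentile 20.7. These medians and counts are from the main setting and can shift with the centring. Median centring over all spots moved the median of all genes in the difference to -0.74. In the main setting, single members were called in both directions. The effector gene BAX (-2.40 ± 0.06) and the cytochrome c gene CYCS (-2.08 ± 0.20) were lower, and the death ligand gene TNFSF10 (2.02 ± 0.29) and the kinase gene DAPK3 (1.49 ± 0.01) were higher. Among the restraining genes, the inhibitor-of-apoptosis genes BIRC3 (2.64 ± 0.06) and XIAP (1.80 ± 0.18) and TNFAIP3 (1.49 ± 0.21) were higher, and the kinase gene AKT1 (-1.14 ± 0.39) was lower. Of the genes past both size rules, 5 were in the promoting list and 4 in the restraining list. The miR-21 target list shares 5 genes with the promoting list and 2 with the restraining list.

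Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had the highest median difference of the 21 lists tested, 1.65, with 50 of 61 members higher and 1 lower. H2BC13 (2.92 ± 0.26), H4C5 (2.82 ± 0.28), H2BC9 (2.66 ± 0.41) and H2BC26 (2.61 ± 0.21) had the largest differences. The list's IP over total was 1.07 in miR-21 cells and -0.47 in EV cells. In miR-21 cells it was -0.56 with median centring. With median centring its difference was -0.13, or 0.61 relative to all genes, and above all random lists. It then lay below the median of known miR-21 targets, so its first rank depended on the centring. Genes of the Argonaute and microRNA machinery had a median of 1.17, with 11 of 20 higher and 0 lower, led by DICER1 (3.07 ± 0.13), CNOT1 (2.59 ± 0.01), DDX6 (2.11 ± 0.06) and PABPC1 (2.01 ± 0.08). Their median was -0.22 with median centring, or 0.52 relative to all genes. ZNF genes had a median of 0.28, with 85 of 319 higher and 9 lower, and -0.44 with median centring, or 0.31 relative to all genes. ZNF727 (3.46 ± 0.30) was the third largest among them. The medians of the histone and ZNF lists exceeded all random lists, and that of the microRNA machinery lay at percentile 99.99. Genes of oxidative phosphorylation (median -0.48, 0 higher and 11 lower of 50, percentile 0.01) and of the mitochondrial ribosome (-0.36, 5 higher and 20 lower of 75, percentile 0.125) were lower as groups, with NDUFB3 at -2.23 ± 0.27, NDUFB6 at -2.11 ± 0.19, MRPL33 at -2.78 ± 0.34 and MRPL40 at -1.80 ± 0.15. MRPL20 went the other way at 1.93 ± 0.12. Targets of miR-17-92 had a median of 0.32 (10 higher and 1 lower of 31), at percentile 97.2 and inside the middle 95% of random lists, and -0.69 with median centring, -0.10 with median centring over probes above background and -0.20 with both populations brought to the same spread, with TNRC6A at 1.94 ± 0.01 and RBL1 at 1.89 ± 0.28 higher and DUSP2 at -1.80 ± 0.11 lower. Ribosomal protein genes had a median of 0.24 (14 higher and 4 lower of 83, percentile 39.0), but -0.21 with the processed signals, -1.95 with median centring and -1.37 with median centring over probes above background, with RPS24 at 2.54 ± 0.22. T-cell receptor signalling genes had 0.12 (6 higher and 4 lower of 37, percentile 77.4), and -0.96 and -0.37 with the 2 kinds of median centring, with RASGRP1 at 2.20 ± 0.06 and PAG1 at 2.11 ± 0.11, both also in the miR-21 target list.

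**Figure D3:**
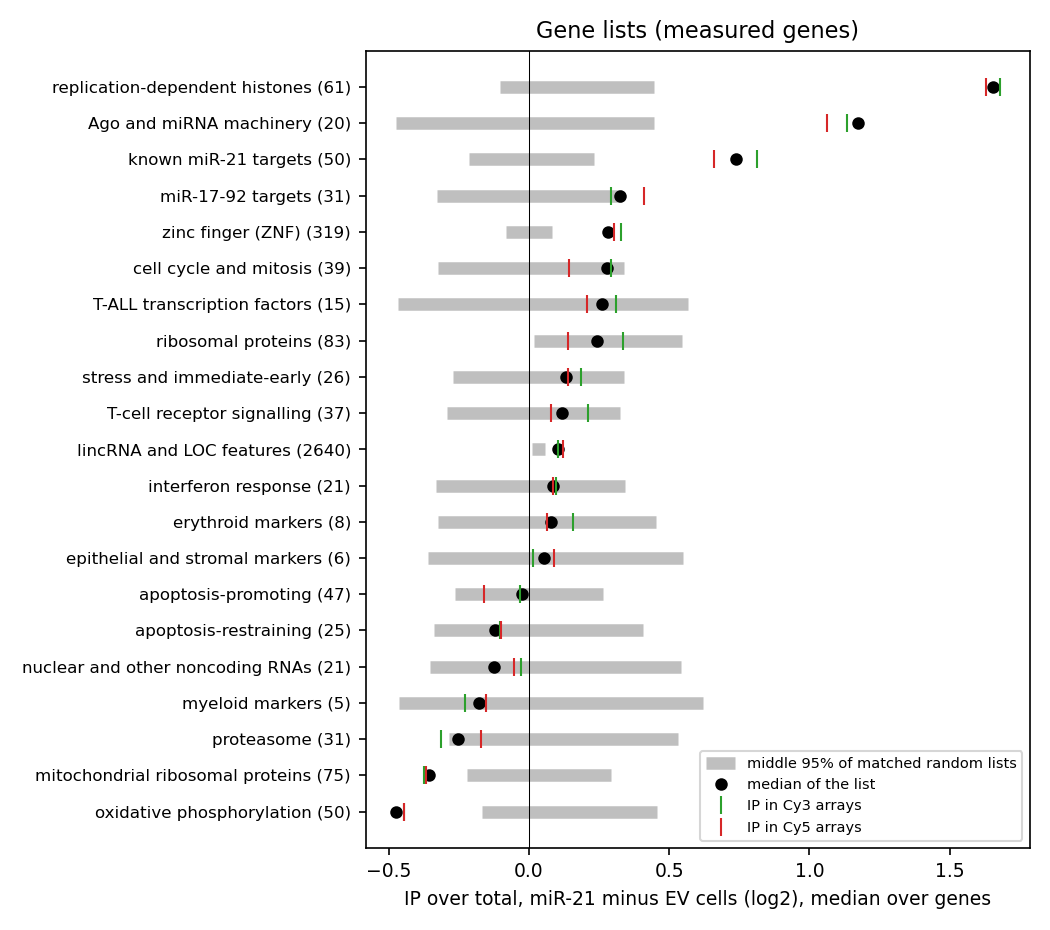
For each gene list with at least 5 measured genes (number in parentheses), the black point is the median log2 difference in IP over total (miR-21 minus EV cells), the coloured ticks are the medians in each dye orientation, and the grey bar spans the middle 95% of 10000 random lists matched on expression. The medians of 5 lists lie above the bar, from 0.10 to 1.65, and those of 2 lie below it, at -0.36 and -0.48; with median centring over all spots the 5 higher medians turned negative and stayed above the middle 95% of their random lists.

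Total RNA was compared between the populations to see which transcripts differed in level. The call was lower in miR-21 cells for 837 of 19357 genes and higher for 126. This split rested on the scaling: 275 were lower and 2489 higher with median centring, 1444 and 1570 with the scanner software's processed signals, 688 and 587 with each channel set to its 75th percentile, and 712 and 543 with median centring over probes above background. The median of all genes was 0.02 in the main setting and 0.34, 0.13, 0.27 and 0.05 in these. The lowest gene was APPL1, an endosomal adaptor gene, at -2.94 ± 0.01, followed by CDK6 (-2.72 ± 0.05), the iron regulatory gene IREB2 (-2.52 ± 0.09), PCGF5 (-2.48 ± 0.07), the retinoblastoma gene RB1 (-2.42 ± 0.05) and SOCS4 (-2.35 ± 0.01). RPS6KA3 (-2.36 ± 0.07), the mitotic kinesin gene KIF14 (-2.30 ± 0.01), ZNF37A (-2.24 ± 0.06) and the Polycomb gene SUZ12 (-2.21 ± 0.02) were next. RPS6KA3 had only -0.30 at its other probe. Among the highest were the histone gene H2BC26 (1.53 ± 0.10), the argininosuccinate synthase gene ASS1 (1.46 ± 0.08), UNCX (1.60 ± 0.39), TBX1 (1.35 ± 0.04), PAQR6 (1.58 ± 0.41), KRTAP19-2 (2.83-fold), EMILIN1 (1.35 ± 0.11), the stress-induced glutathione-degrading enzyme gene CHAC1 (1.30 ± 0.06) and SPNS3 (1.24 ± 0.05).

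Known miR-21 targets were among the groups with lower total RNA. Of 50 measured members, 11 were lower and 0 higher, with a median of -0.28 at percentile 0.11 of random lists. PIKFYVE had -1.88 ± 0.14 and PBRM1 -1.82 ± 0.02, whereas SPRY2 had 0.51 ± 0.01. The list's median was 0.13 with median centring, or -0.21 relative to all genes, at percentile 0.27. Targets of miR-17-92 had a median of 0.10 (percentile 64.5). Apoptosis-promoting genes had a median of 0.10 (percentile 63.5), with BNIP3L (-1.43 ± 0.02), PDCD4 and PDCD10 (-1.09 ± 0.04) lower and 0 higher of 49. Restraining genes had a median of 0.09 (percentile 65.0), with BIRC3 (-1.49 ± 0.04) and XIAP (-1.30 ± 0.09) lower and 0 higher of 25.

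IP RNA, compared between the populations in the same way, was higher in miR-21 cells for 1434 of 16888 genes and lower for 1132; with median centring the split was 452 and 2985, and with median centring over probes above background 935 and 1816. Known miR-21 targets had a median of 0.32 (10 higher and 2 lower of 55, percentile 99.8), or -0.02 with median centring, which is 0.32 relative to all genes. Targets of miR-17-92 were at least as high, with a median of 0.42 (10 higher and 1 lower of 35, percentile 99.8), or 0.10 with median centring. Histone genes had 1.91 (51 higher and 1 lower of 61, 100th percentile), with H2BC26 at 4.14 ± 0.32. The median of all genes was -0.34 with median centring and 0.18 with 75th percentile scaling. Genes of oxidative phosphorylation had -0.56 (0 higher and 12 lower of 50, below all random lists), with NDUFB3 at -2.36 ± 0.01.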

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

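The spike-in test of the spread, the IP-channel tests of the miR-21 targets and of the miR-17-92 targets and the IP-channel test of the lower genes were chosen after the results they bear on had been seen, and bringing both populations to the same spread and recounting opposed genes with median centring were added after the data were seen.

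Several genes had IP over total above 0 in every array of one population and below 0 in every array of the other, by at least 1.5-fold each way. The difference between populations was not tested, since each is 1 sample. ADAMTS7 differed by 3.94 (2.54 in miR-21 cells, -1.40 in EV cells), LINC01001 by 3.88 (2.48 and -1.40) and LCE1D by 3.69 (2.33 and -1.36); these 3 lay at mean log2 signals of 15.95 to 16.46, and with median centring they differed by 1.52, 1.51 and 1.385 (0.35, 0.34 and 0.25 in miR-21 cells), no longer 1.5-fold each way. GABARAPL2 differed by -3.28 (-1.69 and 1.60), ZMYND19 by -3.12 (-1.63 and 1.49), CIAO2A by -3.06 (-1.47 and 1.60), ERG28 by -3.03 (-1.54 and 1.49), ORC6 by -2.88 (-1.62 and 1.26), CENPB by -2.85 (-1.46 and 1.38), UNC50 by -2.83 (-1.67 and 1.16), UBE2N by -2.79 (-0.67 and 2.13) and PDE6D by -2.68 (-1.86 and 0.82). The replication-dependent histone list lay above its random lists in miR-21 cells (1.07) and below the middle 95% of them in EV cells (-0.47), with a median difference over its genes of 1.65 that was likewise not tested; with median centring it had -0.56 and -0.30. Over all genes, 275 went opposite ways by this measure, 155 of them higher in miR-21 cells and 120 lower; with median centring these were 3 and 625.

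The first pattern weighed is the wider spread of IP over total in miR-21 cells, with an SD over genes 1.51 times that of EV cells. Compression of ratios on the EV arrays is argued against by the spike-in controls, whose slope of observed on nominal log ratio was 0.860 on the EV arrays and 0.882 on the miR-21 arrays, a ratio of 0.976. Their intercepts (log10 red over green) bear on the centring instead. With the IP in Cy3 and in Cy5 they were -0.214 and 0.471 on the miR-21 arrays, and 0.426 and -0.278 on the EV arrays. They thus ran opposite ways in the populations, toward the IP in miR-21 cells and toward total RNA in EV cells. No setting was centred on them. Dim probes as the source cannot be told apart from a real difference: among the brightest 4096 genes the ratio of SDs was 1.45, between the bounds set for either outcome. Unselected RNA carried over in the EV immunoprecipitate remains open and may account for part of the spread, since the slope of EV on miR-21 ratios was lower among depleted than among enriched genes, by 0.413 and 0.318 in the 2 orientations, as carry-over would give; it cannot turn a sign, so it leaves the opposed genes unexplained, though which genes these are depends on the centring. An effect of miR-21 on Ago2 loading, or a difference between the 2 immunoprecipitations, stays open and untested.

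The second pattern is the higher IP over total of known miR-21 targets in miR-21 cells. A difference in spread as the whole of it is argued against, because after both populations were brought to the same spread the list's median of 0.36 still lay at percentile 99.97 of random lists. Lower total RNA alone is argued against by IP RNA of the targets, with a median of 0.32 at percentile 99.84. A change common to targets of other microRNAs is not settled by the main setting, where the miR-17-92 list's median lay 0.416 below that of the miR-21 list. The gap of 0.153 between dye orientations covers technical error only, not how medians vary with the genes listed. Random lists matched to the miR-17-92 list had medians of -0.33 to 0.33 in the middle range used here. The miR-17-92 list itself lay at percentile 97.2. After both populations were brought to the same spread it fell to percentile 10.1, against 99.97 for the miR-21 list. However, that scaling multiplies all ratios of a population by the same factor, so it lowers the difference of lists already enriched in EV cells. The EV median was 1.18 for the miR-17-92 list and 0.48 for the miR-21 list. The contrast therefore reflects in part these EV ratios and cannot decide on a common change. Lists not chosen as miR-21 targets also rose: in the main setting histone genes had 1.65 and microRNA machinery 1.17, above the 0.74 of miR-21 targets. With median centring over all spots both lay below the miR-21 targets. Random lists were matched on mean signal only, not on transcript length, so a rise shared by other features of these transcripts is not controlled. For the IP RNA a common change remains open: the miR-17-92 list had 0.4212 at percentile 99.77, and the miR-21 list minus it was -0.0963. So the gap in the ratio came from total RNA (0.10 against -0.28). A common rise in IP RNA together with lower total RNA of miR-21 targets could therefore give the pattern, and binding of more targets by Ago2 loaded with miR-21 stays open and untested, with slide and population the same split and 1 sample each.

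The third pattern is the excess of lower over higher genes in total RNA of miR-21 cells. A slide or hybridisation effect that acts on both dyes of these spots is argued against, as the 822 lower genes with measured IP RNA had a median IP difference of -0.007, or 0.00583 of their total RNA difference. Whether there was an excess depended on the normalization: lower over higher was 4.84 with quantile normalization and 1.17 with 75th percentile scaling. Of the called genes, 13.1% were higher in the main setting, but 52.1% with the processed signals and 90.05% with median centring over all spots. Loss of signal at single probes cannot be told apart from loss of the transcript, since 218 other probes of 187 of these genes had a median of -0.59, between the bounds set for either outcome. An effect of miR-21 on these transcripts and a difference in labelling of total RNA both stay open and untested.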

How the results depend on the processing

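Median centring over probes above background and scaling to the same spread were chosen after seeing the data, as were all alternatives for IP RNA and the list medians in total and IP RNA under quantile and 75th-percentile scaling; the others were set at the start. No paired analysis was possible because each population has 1 sample and no test was run. The comparison by miR-21 sites and its other settings were not run, as they need transcript sequences. Of the counts and main values, 111 recomputed values stayed within 1.5 times the main count or within the technical spread, and the rest are given here; the cause was not tested unless stated. The filters on dim probes, each dye orientation, the mean of probes and outlier spots moved no count by over 1.5 times. Of 534 values of single genes, 259 moved by more than the technical spread, with the sign kept or the gene not past the size rule. Sign changes numbered 10, 4 of them for genes past the size rule: with median centring BTG2 had -0.28 and SKP2 -0.0063 in the difference, and with scaling to the same spread BTG2 had -0.69 and ZNF367 -0.066.

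Median centring over all spots, which moved the median of all genes in the difference to -0.74, gave for IP over total 1127 higher and 5576 lower genes in miR-21 cells, 352 lower in EV cells, 397 higher and 6421 lower in the difference and 298 past both rules. It gave 2489 higher and 275 lower in total RNA, and 452 and 2985 in IP RNA. The list medians in the difference became -0.11 for known miR-21 targets, -0.22 for Argonaute and microRNA machinery, -0.33 for lincRNA and LOC features, -0.13 for histones and -0.44 for ZNF genes, all reversed and all still above the middle 95% of their random lists. By construction it centres on spots that include those near background and leaves trends with signal in place. Centring over probes above background gave 3384 lower in miR-21 cells, 3335 lower in the difference, 853 past both rules, 543 higher in total RNA, 935 higher and 1816 lower in IP RNA, and a miR-21 target median of 0.48. The scanner software's processed signals, also centred on the median over all spots, gave 3529 lower in miR-21 cells, 1152 lower in EV cells, 2882 lower in the difference, 1570 higher and 1444 lower in total RNA, 2563 and 2039 in IP RNA, a miR-21 target median of 0.94 and a reversed lincRNA median of -0.005447. An offset of 10 gave 287 higher and 1357 lower in total RNA, 2228 higher in IP RNA and a target median of 1.05. Scaling to the same spread gave a target median of 0.36, and 75th percentile scaling 587 higher in total RNA. A threshold of 1.5-fold, which admits more genes by construction, gave 3908 higher and 3432 lower in miR-21 cells, 3009 and 2211 in EV cells, 3554 and 3127 in the difference, 2510 past both rules, 1511 and 2397 in total RNA, and 3222 and 2713 in IP RNA. Lists outside the middle 95% of random lists in the difference numbered 7 of 21, and 7 to 9 under the alternatives. Signal over background limits which genes could be compared: 53.5% to 61.9% of spots per channel were well above it in the miR-21 arrays and 72.2% to 82.3% in the EV arrays.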

Other observations

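Median centring over probes above background and equal spread were chosen after the data were seen; the test of known targets was not. Groups outside the main comparisons also differed in total RNA. Stress and immediate-early genes had a median of 0.28 in miR-21 cells over EV cells (2 higher and 1 lower of 26, percentile 99.55), with CHAC1 at 1.30 ± 0.06 and the stress transcription factor gene ATF3 at 1.22 ± 0.11 higher and the chaperone gene HSPH1 at -1.87 ± 0.01 lower. Histone genes had 0.27 (4 higher and 1 lower of 61, above all random lists), with H4C6 at 1.35 ± 0.23 and H4C11 at 1.25 ± 0.35. Nuclear and other noncoding RNAs had 0.20 (percentile 98.2), with HCG18 at -1.24 ± 0.35 as the 1 lower member of 21. Cell cycle genes had -0.20 (0 higher and 6 lower of 39, percentile 0.56), with the mitotic genes KIF11 (-1.85 ± 0.02), CENPF (-1.61 ± 0.16) and MKI67 (-1.43) lower; with median centring over probes above background their median was 0.22, or 0.17 relative to all genes, at percentile 1.10, and with median centring over all spots 0.51. Ribosomal protein genes had -0.22 (0 called of 83, percentile 0.205), but 0.08 with quantile normalization, 0.31 with 75th percentile scaling and 0.92 with median centring. The lincRNA and LOC features had -0.17 in total RNA (26 higher and 113 lower of 3614, below all random lists) and 0.10 in the difference of IP over total (243 higher and 102 lower of 2640, above all random lists); with 75th percentile scaling the former was 0.17, or -0.09 relative to all genes, and with median centring the former was 0.005046 and the latter -0.33.

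In the difference of IP over total, cell cycle genes had a median of 0.28 (7 higher and 4 lower of 39, percentile 94.8), with MKI67 at 3.29 ± 0.15; the median was -1.07 with median centring and -0.08 with both populations brought to the same spread. Interferon response genes had 0.09 (4 higher and 2 lower of 21, percentile 71.9) and -0.54 with median centring, with EIF2AK2 at 2.27 ± 0.05 and USP18 at -1.81 ± 0.02. T-ALL transcription factor genes had 0.26 (3 higher and 0 lower of 15, percentile 80.0) and -0.64 with median centring, with MYB at 2.33 ± 0.17, RUNX1 at 1.93 ± 0.20 and IKZF1 at 1.69 ± 0.16. Stress genes had 0.13 (3 higher and 2 lower of 26, percentile 75.3), and -1.15 with median centring and -0.36 with both populations brought to the same spread. Proteasome genes had -0.25 (3 higher and 4 lower of 31, percentile 3.38), and nuclear and other noncoding RNAs had -0.13 (3 higher and 5 lower of 21, percentile 16.9). Of the lists of markers of other cells, fewer members could be measured in miR-21 cells than in EV cells (B-cell 4 against 11, myeloid 5 against 11, erythroid 8 against 10, epithelial and stromal 6 against 9). Of the B-cell list 4 of 14 members were measured in all RNAs, of the myeloid list 5 of 18 (median -0.18, percentile 18.7), of the erythroid list 8 of 15 (0.08, percentile 62.3), and of the epithelial and stromal list 6 of 16 (0.05, percentile 46.2). The last held the 1 call among these lists in this comparison, the intermediate filament gene VIM at 1.71 ± 0.24, which many cell types express. With median centring the erythroid and epithelial medians were -0.33 and -0.29, and with median centring over probes above background the myeloid median was 0.10.

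The hypothesis that known miR-21 targets were lower in total RNA of miR-21 cells, fixed before the test, was borne out in these arrays: the list's median lay at percentile 0.11 of random lists with the IP in Cy3 and below all of them with the IP in Cy5. Loss of target transcripts when miR-21 is overexpressed would give this result, but the percentile does not single it out. Of 22 lists tested in total RNA, 3 lay above and 4 below the middle range used for random lists. Besides the miR-21 targets, the lower ones were cell cycle genes (percentile 0.56), ribosomal protein genes (0.205) and lincRNA and LOC features (below all random lists). None of these was chosen as a list of miR-21 targets. With 1 sample per population on separate slides, a difference between the cultures or slides stays open.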
